A study of Cyprinodon variegatus with 38 samples.

How the data were processed

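Liver RNA of 38 fish was labelled with Cy3 and hybridised to 1-colour Agilent arrays of 15208 probes. Spot intensity values were deposited as scanner output from Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and the processed signal was background subtracted and detrended within each array, per the file headers. The authors also deposited a value table on the log2 scale. Set against the scanner signals, each of its columns had the same ranks as that array's processed signal (lowest Spearman rho 1.0), and its column medians ran from 5.29 to 5.32 at 7 days and from 4.73 to 4.77 at 14 days, so it was used only within a day; how it was normalised is not given in the sources used here.

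Control spots and the 0.142% of spots with outlier marks were left out. Signals were put on the log2 scale and each array's 75th percentile was subtracted. Because under 50% of the probes were well above background on 26 arrays, the percentile was taken over the 1644 probes well above background on all 38 arrays. That percentile varied 28.7-fold between arrays. Probes were tested where they were well above background on every female array of at least 1 group and had an unmarked spot in every group, which left 7422. All 36 female arrays were fitted as group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are differences of these log2 values. Arrays came from 6 slides scanned in 2 sessions, with the 2 days of sampling kept apart for the females. The slide entered as a fixed block within each day, as a random block (correlation 0.00931) and by comparison within a slide. Other values were computed with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

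The fit was tested on simulated data made from the real probes' means and spread, with 200 changed probes among 7422. The noise was normal and independent, without slide effects, dim or outlying arrays or probes that vary together, so the shares may differ on real arrays. In 7-day Corexit it recovered 4.41% of probes changed by a log2 difference of 1, 37.9% at 2 and 90.9% at 4. In 14-day high CEWAF the shares were 10.3%, 33.3% and 87.9%, and in 14-day Corexit 2.94%, 24.2% and 83.3%. False calls numbered 6 in 7-day Corexit, 3 in 14-day high CEWAF and 8 in 14-day Corexit.

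The groups, tests, rule for named probes and most alternatives were fixed before the data were examined. That rule took genes with the largest changes by adjusted p from named genes and from fixed gene lists. Since the files do not pair probes with genes, the list tests and the egg protein values by sex were not run, and the rule was applied to probe IDs, at most 2 higher and 2 lower per comparison, or the smallest p where none passed, plus the 2 probes called in the most treatment comparisons. The labels describe 2 control samples left out at 14 days for low dye incorporation, whereas 4 control and 2 Corexit arrays of that day were used here. Alternatives changed the background correction, scaling, filter, slide, tank letter, sex, variance model, array weights and arrays. Normexp background correction added an offset of 50 to every signal, while the median processed signal of an array ran from 5.95 to 112. The offset shrinks log2 differences of dim probes, more so on dim arrays. A lower count under normexp therefore cannot tell false calls from shrunken differences. Under it the median probe in 14-day Corexit lay higher by 1.82 than in control. Highest correlation between arrays was 0.957, and no array was a copy of another. Tank letters were not taken to pair fish. Overlaps of calls were set against 100 simulations of unchanged groups, made by reassigning the fit's residuals to arrays, with lists of the same sizes ranked by limma's moderated statistic.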

Results

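Liver transcripts were measured in adult sheepshead minnows (Cyprinodon variegatus), a small estuarine fish, after 7 or 14 days in seawater, in water-accommodated oil fractions, or in dispersant. HEWAF was the fraction made by mechanical mixing of oil, CEWAF the fraction made with chemical dispersant, and Corexit the dispersant alone. The low and high oil doses were 1 and 10 mg per L and the dispersant dose was 1 mg per L. The 38 arrays fell into 10 groups. At 7 days, control, low HEWAF, high HEWAF, Corexit, low CEWAF and high CEWAF had 4 arrays each. At 14 days, control, high HEWAF and high CEWAF had 4 arrays each and Corexit had 2. Each array held the liver RNA of 1 fish, and each fish of a group came from a different tank. Of the fish, 36 were female and 2 were male, 1 in each control group, and the comparisons used the females, so that each control group had 3 arrays. The 15208 probes are 60-base sequences that the files do not pair with genes, so probes are given by their ID and no gene group could be tested.

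Signal over background differed widely between arrays. The share of probes well above background ranged from 16.7% to 60.8% of the 15208 probes, with a median of 49.1% at 7 days and 28.3% at 14 days. In female fish it was 54.2% ± 3.19 (SD, n = 3) in the 7-day controls, 44.9% ± 9.72 (SD, n = 4) in 7-day Corexit, 37.2% ± 11.8 (SD, n = 3) in the 14-day controls and 22.6% ± 4.00 (SD, n = 4) in 14-day high CEWAF. No probe was saturated on any array. The number of arrays limits the precision of every value below.

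**Figure D1:**
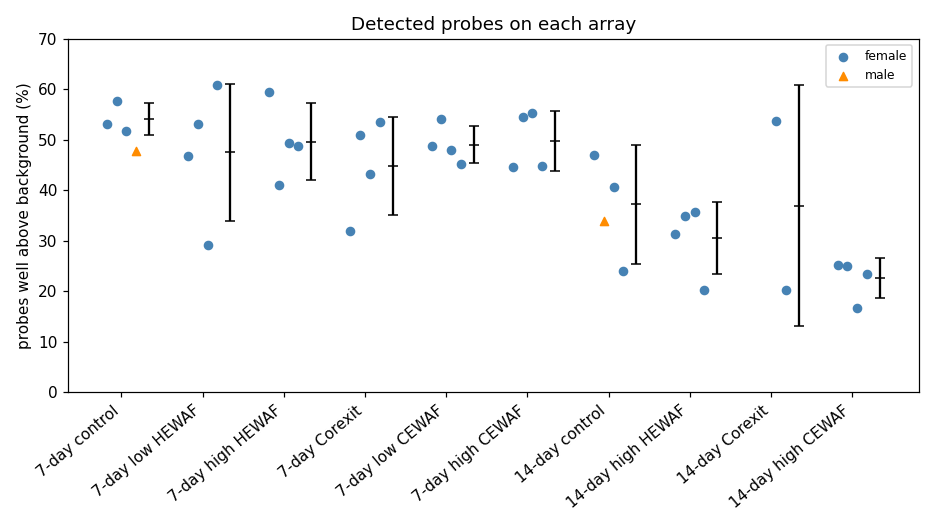
Share of probes well above background (percent, y axis) on each array, by group (x axis). Points are arrays, triangles are the male fish, and bars give the mean and SD of the female arrays; the values run from 16.7% to 60.8%, and the 14-day high CEWAF arrays lie at or below 25.3%.

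The first comparison asked which transcripts differed after 7 days in HEWAF. In low HEWAF, 0 of 7422 probes differed from the 7-day control by limma at an adjusted p under 0.05, and 503 had an unadjusted p under 0.05. The probe with the smallest p, SHM_EA_10150, had a log2 difference of -3.94 ± 0.77 (SE) and an adjusted p of 0.134, and was well above background on 3 of 4 low HEWAF arrays. In high HEWAF, 6 probes were lower and 0 higher than in control. SHM_EA_23446 (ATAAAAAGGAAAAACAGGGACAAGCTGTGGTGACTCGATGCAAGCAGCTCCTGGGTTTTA) fell by 5.31 ± 0.90 on the log2 scale (SE, limma adjusted p = 0.0140), from -2.77 ± 0.57 (SD, n = 3) in control to -8.07 ± 1.60 (SD, n = 4), where it was well above background on 2 of 4 arrays. SHM_EA_17460 fell by 7.56 ± 1.54 (SE, limma adjusted p = 0.0419) and was well above background on 1 of 4 high HEWAF arrays. Where only some arrays of a group measured a probe, here and below, the size of the difference rests in part on signal near background. The median probe lay lower by -0.30 in low HEWAF and -0.36 in high HEWAF, and relative to that shift SHM_EA_23446 was lower by -4.95. In high HEWAF 0 probes passed with normexp background correction or in the authors' value table, 10 higher and 9 lower passed when its groups were compared alone, and 1688 passed with array weights. Low HEWAF had 2 higher and 69 lower probes with array weights. With slide as a fixed block 0 probes passed in high HEWAF and 1 in low HEWAF, and within slide 1 the counts were 1, from 1 high HEWAF array against 3 controls, and 2, from 3 arrays against 3. Wherever a slide held 1 array of a group, that array was taken to vary like the other groups. Without high HEWAF replicate a 10 probes passed, and without any other single array of that comparison 0 passed; without 7-day high CEWAF replicate c, an array that stood apart and entered through the shared spread, 10 passed. Between the high and low HEWAF doses, 0 probes differed by limma and 405 had an unadjusted p under 0.05, with 1 call within slide 1 (1 high against 3 low arrays) and 0 within slide 2 (3 against 1).

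Corexit alone at 7 days gave 68 lower probes and 1 higher probe than control. SHM_EA_46691 (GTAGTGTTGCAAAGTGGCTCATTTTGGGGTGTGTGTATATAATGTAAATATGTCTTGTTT) fell by 5.31 ± 0.96 on the log2 scale (SE, limma adjusted p = 0.00990), and was well above background on 2 of 4 Corexit arrays against 3 of 3 control arrays. SHM_EA_12419 fell by 5.28 ± 1.04 (SE, limma adjusted p = 0.0169) and was well above background on 3 of 4 Corexit arrays. The higher probe was SHM_EA_29748, which rose by 3.30 ± 0.82 (SE, limma adjusted p = 0.0468) from -5.97 ± 1.64 (SD, n = 3) to -2.67 ± 0.70 (SD, n = 4). All of these probes separated the Corexit from the control arrays without overlap. The median of all tested probes was lower by -0.60, and the split depended on the scaling: 8 lower and 3 higher probes passed after median centring, and 14 lower and 0 higher after quantile normalisation. With normexp background correction, in the authors' value table and with the groups compared alone 0 probes passed, and with array weights 2418. All 3 female controls shared slide 1, which held no Corexit array, and 0 probes passed with slide as a fixed block; no slide held both groups. Leaving out control replicates a, b and c in turn left 3, 1 and 15 probes, and leaving out Corexit replicates a, b and d left 27, 28 and 12. Without 7-day high CEWAF replicate c 307 probes passed.

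Low CEWAF at 7 days gave 106 lower and 2 higher probes. SHM_EA_42234 (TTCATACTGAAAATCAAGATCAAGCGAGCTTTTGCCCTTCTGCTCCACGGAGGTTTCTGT) rose by 5.98 ± 1.55 on the log2 scale (SE, limma adjusted p = 0.0467) against 2 controls, 1 control spot having been left out for an outlier mark, and SHM_EA_48178 rose by 2.30 ± 0.48 (SE, limma adjusted p = 0.0185) with 4 of 4 arrays above all 3 controls. SHM_EA_41308 fell by 7.78 ± 1.67 (SE, limma adjusted p = 0.0185) and was well above background on 1 of 4 low CEWAF arrays, but its control arrays varied by 4.48 (SD, n = 3) and overlapped the low CEWAF arrays. The median probe was lower by -0.45, and with median centring the split became 42 lower and 55 higher. With normexp background correction 0 probes passed, 13 lower and 46 higher passed in the authors' value table, and with array weights 1999 in all. All 3 female controls were on slide 1, which held no low CEWAF array, so no slide held both groups and slide cannot be told apart from treatment within a slide. A fixed block for slide left 1 probe. Without control replicates a and b in turn 2 and 0 passed, without low CEWAF replicates a and b 62 and 38, and without 7-day high CEWAF replicate c 329.

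High CEWAF at 7 days gave 11 lower and 0 higher probes. SHM_EA_12419 fell by 5.30 ± 1.04 on the log2 scale (SE, limma adjusted p = 0.0325) and was well above background on 2 of 4 high CEWAF arrays. SHM_EA_13437 was not well above background on any of the 4 high CEWAF arrays and was at least 5.06-fold lower than in control (limma adjusted p = 0.00824). Such bounds set the brighter group's mean against the lowest signal well above background on the dimmer group's arrays. The median probe was lower by -0.35, and median centring gave 7 lower and 17 higher probes. With normexp background correction and with the groups compared alone 0 probes passed, 4 lower and 17 higher passed in the authors' value table, and with array weights 1986 in all. Replicate c decided the count: 289 probes passed without it. Without control replicates a, b and c 4, 0 and 0 passed, and without high CEWAF replicates a and d 0 and 5. With slide as a fixed block 0 probes passed, and within slide 1, where replicate c was the 1 high CEWAF array against 3 controls, 577 passed.

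Calls of the 7-day comparisons overlapped, and all of these comparisons shared their 3 controls. Corexit and low CEWAF had 22 lower probes in common, against 0.971 for independent lists of these sizes and 15.1 (3 to 35 in 95% of 100 simulations) for the lists of the same sizes from unchanged groups sharing the controls. High HEWAF shared 5 of its 6 lower probes with low CEWAF, against 0.0857 for independent lists and 2.29 (0 to 6) in the simulations, and 2 with Corexit, against 0.0550 and 2.06 (0 to 5). These overlaps lay within the simulated ranges. Of the 2 probes called in 3 of the 8 treatment comparisons, SHM_EA_23446 was lower at 7 days by -5.31 in high HEWAF, -5.05 in Corexit and -4.50 in low CEWAF on the log2 scale. SHM_EA_51644 was lower by -2.91 in 7-day Corexit and -1.96 in 7-day low CEWAF, and at least 2.04-fold lower in 14-day high CEWAF, where it was not well above background on any array.

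Chemically and mechanically dispersed oil were compared at matched doses at 7 days. Between low CEWAF and low HEWAF, 5 probes were higher and 11 lower in CEWAF. SHM_EA_31246, well above background on 3 of 4 low HEWAF arrays, was higher by 2.83 ± 0.50 on the log2 scale (SE, limma adjusted p = 0.00941), and SHM_EA_43588, not well above background in low CEWAF, was at least 2.91-fold lower (limma adjusted p = 0.00941). The split was 48 higher and 31 lower after median centring and 22 and 3 in the authors' value table, 0 probes passed with normexp background correction or with the groups compared alone, and 2 probes passed with slide as a fixed block. Without low HEWAF replicate c 7 passed, and without low CEWAF replicates a, b and d 5, 6 and 7, and without 7-day high CEWAF replicate c 78. At the high dose, 0 probes differed by limma and 556 had an unadjusted p under 0.05; 18 probes passed without high CEWAF replicate c and 2 within slide 2, where 1 high CEWAF array met 3 high HEWAF arrays. With all arrays kept, high CEWAF had 13 higher and 4 lower probes than high HEWAF after median centring, and 32 higher and 129 lower with array weights. Between high and low CEWAF, SHM_EA_26839 and SHM_EA_43491 were at least 2.65-fold and 2.18-fold higher at the high dose (limma adjusted p = 0.00451 and 0.0334), neither being well above background at the low dose. With normexp background correction, quantile normalisation, the authors' value table or the groups compared alone, and within slide 3, 0 probes differed between these doses, and leaving out single arrays gave 0 to 5.

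**Figure D2:**
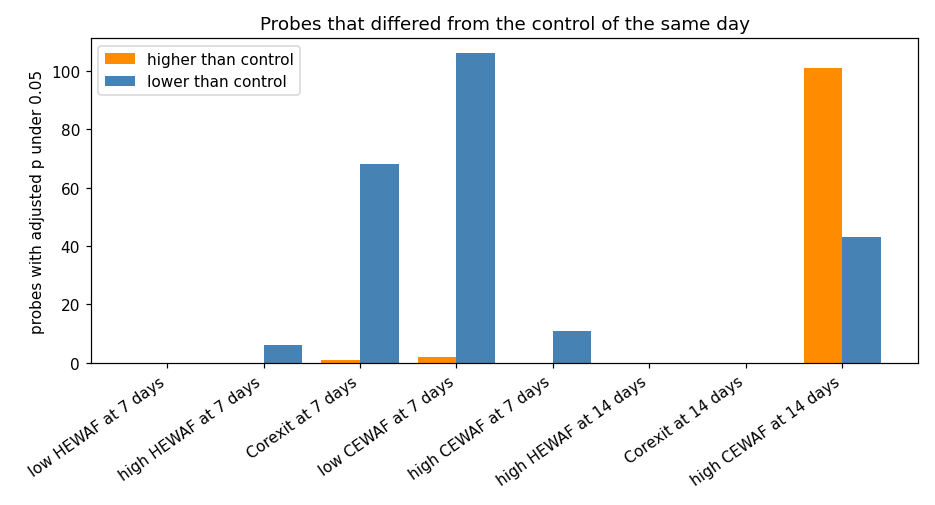
Number of probes with an adjusted p under 0.05 (y axis) that were higher or lower than the control of the same day, for the 8 treatment comparisons (x axis). Low CEWAF at 7 days had 106 lower probes and high CEWAF at 14 days had 101 higher probes.

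After 14 days, high HEWAF and Corexit had 0 called probes by limma, with 323 and 632 at an unadjusted p under 0.05. In Corexit, which had 2 arrays, SHM_EA_20910 had the smallest p, with a log2 difference of 3.24 ± 0.63 (SE, limma adjusted p = 0.105) from a control group in which 1 of 3 arrays was well above background, and 76 probes passed without replicate c, when the lone remaining array, replicate d, was taken to vary like the other groups. On that array 20.1% of the probes were well above background. Quantile normalisation gave 22 higher and 48 lower probes in Corexit and 1 and 6 in high HEWAF. High HEWAF had 3 calls within slide 4 and 4 within slide 6, and Corexit 0 within slide 5, each from 2 treated arrays against 1 control array.

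High CEWAF at 14 days gave 101 higher and 43 lower probes. SHM_EA_22919 (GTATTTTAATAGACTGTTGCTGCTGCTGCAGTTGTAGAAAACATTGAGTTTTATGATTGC) rose by 7.19 ± 1.51 on the log2 scale (SE, limma adjusted p = 0.0105), from -8.50 ± 2.16 (SD, n = 3) in control, where it was well above background on 1 of 3 arrays, to -1.30 ± 2.08 (SD, n = 4). SHM_EA_42234, also higher in low CEWAF at 7 days, rose by 6.88 ± 1.55 (SE, limma adjusted p = 0.0168) to 4.88 ± 0.65 (SD, n = 4), against 2 control arrays, since 1 control spot had been left out. SHM_EA_11083 was not well above background on any high CEWAF array and was at least 2.20-fold lower (limma adjusted p = 0.0149), and SHM_EA_13045 fell by 3.11 ± 0.84 (SE, limma adjusted p = 0.0482), with overlapping groups and 1 of 4 high CEWAF arrays well above background. The 101 higher probes averaged 2.56 ± 0.75 (SD, n = 4) relative to the array median in high CEWAF and -0.98 ± 0.31 (SD, n = 3) in control. The number of higher probes was 101 after median centring and 143 after quantile normalisation, while that of lower probes went from 43 to 112 and 592. With slide as a fixed block 43 higher and 10 lower probes passed, within slide 4, with 3 high CEWAF arrays against 1 control array, there were 23 higher and 0 lower, and with normexp background correction 1 probe passed. Without control replicates a and c 66 and 40 probes passed, and without high CEWAF replicates c and d 80 and 34.

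**Figure D3:**
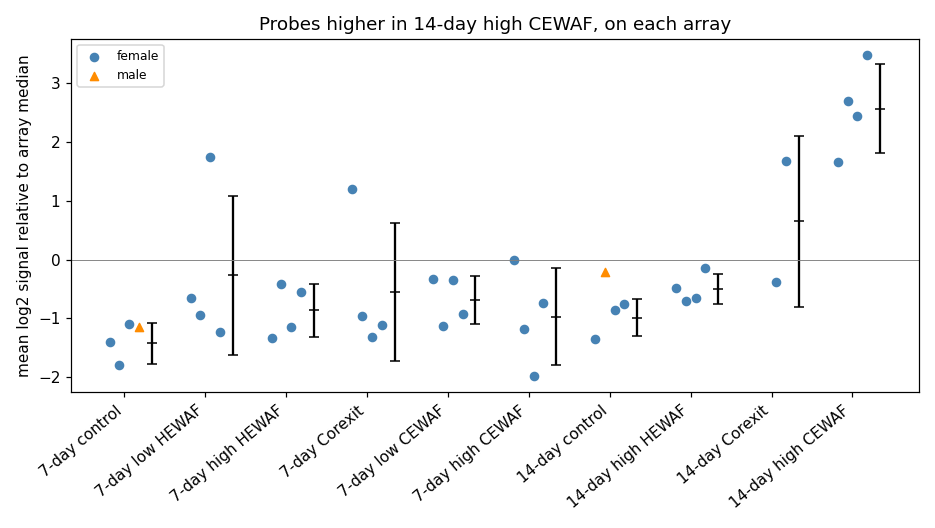
Mean log2 signal of the 101 probes that were higher in 14-day high CEWAF, relative to each array's median (y axis), by group (x axis). Points are arrays, triangles are male fish, and bars give mean and SD of the female arrays; high CEWAF averaged 2.56 at 14 days, and single arrays of 7-day low HEWAF, 7-day Corexit and 14-day Corexit lay at 1.73, 1.20 and 1.68.

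Against high HEWAF at 14 days, high CEWAF had 121 higher and 27 lower probes. SHM_EA_51199 (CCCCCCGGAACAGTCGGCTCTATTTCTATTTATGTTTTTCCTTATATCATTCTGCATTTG) was not well above background in high HEWAF and was at least 25.0-fold higher in high CEWAF (limma adjusted p = 2.63e-05). SHM_EA_42234 was higher by 6.39 ± 1.27 on the log2 scale (SE, limma adjusted p = 0.00616). SHM_EA_37736 was at least 3.16-fold lower in high CEWAF (limma adjusted p = 0.0175). The median probe was higher by 0.24, and the split became 110 higher and 142 lower after median centring. Quantile normalisation gave 194 higher and 456 lower probes, and normexp background correction 18 higher and 0 lower. A fixed block for slide left 48 higher and 7 lower probes, and within slide 4 there were 54 higher and 7 lower. Without high HEWAF replicates a, b, c and d 63, 55, 68 and 236 probes passed, and without high CEWAF replicates c and d 83 and 55.

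The treatment effects at 14 and 7 days were compared directly. The high CEWAF effect differed for 25 probes, of which 24 had the higher effect at 14 days, among them SHM_EA_37837 (limma adjusted p of the difference = 0.0128). At 14 days this probe was not well above background on any control array, and was so on 2 of 4 high CEWAF arrays. Another of the 24, SHM_EA_27007 (limma adjusted p of the difference = 0.0313), was not well above background on any high CEWAF or control array at 14 days. Its 14-day effect thus rests on signal near background. The high HEWAF and Corexit effects differed for 0 probes by limma, with 310 and 1369 at an unadjusted p under 0.05. With slide as a fixed block or with normexp background correction 0 probes passed for high CEWAF, and quantile normalisation gave 13 higher and 75 lower. Leaving out 7-day control replicates a, b and c gave 0, 1 and 1 probes, and 7-day high CEWAF replicates a, b, c and d 8, 14, 217 and 1. Leaving out 14-day control replicates c and d gave 0 and 70, and 14-day high CEWAF replicates a, c and d 94, 1 and 8. The Corexit effect differed for 59 probes without 14-day Corexit replicate c and 14 without 7-day Corexit replicate a, and for 59 without 7-day high CEWAF replicate c, without which the high HEWAF effect differed for 1 probe.

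Across the 7422 probes, which are not independent replicates, the fold changes of Corexit and low CEWAF at 7 days had a Pearson r of 0.774, against 0.554 (0.188 to 0.838 in 95% of simulations) for unchanged groups sharing the controls, and a covariance of 0.744 against 0.310. Corexit and high CEWAF at 14 days had an r of 0.666, against 0.462 (0.0547 to 0.760). Between 7 and 14 days, r was 0.227 for high HEWAF, -0.163 for Corexit and 0.113 for high CEWAF. All 16 correlations computed lay within the range of their simulation. In the 8 control fish, male and female arrays differed in 0 of 7422 probes by limma with time as a covariate, and 561 had an unadjusted p under 0.05. With 2 males, and probes kept by their signal on female arrays, this comparison could miss a difference between the sexes.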

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

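The tests of slide, scaling and dispersant at 7 days, and of slide and array brightness at 14 days, were chosen after the results were seen. So were those of the outlying array, the splits of the arrays and the common floor. The test of signal floor by the share of probes well above background was written down first. Of 82 sets of 4 arrays examined, 10 had 1 array far from the rest, and chance gives about 1 in 20 for independent normal values. Many of these sets shared arrays, and they included probe sets picked for a wide spread and probes picked by their differences. That rate is therefore no test of the number found.

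The first pattern is the 68 probes lower in 7-day Corexit. Slide 1 as the whole cause is argued against inside slide 2, where these probes, measured relative to array medians, averaged -0.765 log2 lower in 2 CEWAF than in 4 HEWAF arrays with no overlap (exact permutation p = 0.0667, the smallest possible), and by the male 7-day control on slide 5 at 1.46 beside 1.46 to 1.58 in the female controls on slide 1. Scaling as the whole cause is argued against by a difference of -1.03 between 8 CEWAF and 8 HEWAF arrays (exact two-sided permutation p = 0.000155). These arrays did not choose the probes, and 1000 random probe sets gave -0.246 to 0.177. Exact p-values over several slides, here and below, ignore slide, and slide 3 held CEWAF but no HEWAF arrays. For Corexit against control itself, median centring gave 8 lower and 3 higher probes. A response to dispersant may be a candidate explanation, as a hypothesis that stays open: CEWAF lay below HEWAF by -1.04 at 7 days without the outlying high CEWAF array (exact permutation p = 0.000155), but by -0.0181 at 14 days (exact permutation p = 0.857), when all 10 treated arrays lay below the 3 controls (difference -0.486, exact permutation p = 0.00350, the smallest possible). The 8 HEWAF arrays at 7 days, at 0.713 to 1.32, also lay below the female controls, which had helped to choose the probes, and the order in which fish were sampled, for which no label was used, stays open.

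The second pattern is the 101 probes higher in 14-day high CEWAF. A signal floor as the whole cause is argued against, since 66.3% of them were well above background on all 4 arrays. All 101 had entered the test through another group. With a common floor on every array, 36 of the 47 still tested were called higher, with a mean effect of 2.33 against 3.57. That fit cannot add to this, since probes could enter it through high CEWAF itself, where they were high. With normexp background correction 1 probe passed in this comparison. Slide as the whole cause is argued against, since 95.5% of the mean effect of 3.62 was left with slide as a block. The same arrays had chosen the probes, and only slides 4 and 5 held both groups, with 1 female control on each. With the block 43 higher and 10 lower probes passed. Array brightness stays open: the 3 dim arrays of other groups lay 2.05 log2 above their group mates in the same probes, over 50% of the effect, as brightness would predict. With brightness as a covariate 79.2% of the effect was left and 87 higher and 32 lower probes passed. Brightness as the whole cause and with a linear effect would not predict that. Without the 4 dim arrays 194 higher and 54 lower passed. That fit cannot decide, since the 3 high CEWAF arrays left were still dimmer than the female 14-day controls. Their scaling percentiles were 3706 to 8911, against 9754 to 12263. Inside high CEWAF the percentiles of replicates a, c, b and d were 8911, 4592, 3706 and 2240. The probes averaged 1.65, 2.43, 2.70 and 3.48 on them relative to array medians, higher the dimmer the array. Brightness is thus not settled.

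The third pattern is 7-day high CEWAF replicate c. A set of 38 probes that vary together lay at -3.20 on this array, against 4.63 to 5.01 on its group mates, and a set of 26 probes at -1.26, against 6.02 to 6.77. A dim array is argued against by 55.4% of its probes being well above background, more than on any group mate, and a swap inside the series by a gap of 4.03 to the next lowest array. This array helped to define the sets, since their probes were picked for a wide spread within groups. A sample of mixed or other tissue was not tested, since no marker genes are named.

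Other arrays far from their group mates were as follows. The log2 scaling percentile was 10.5 on 7-day low HEWAF replicate c. A set of 115 probes averaged 4.03 on 7-day low HEWAF replicate d and 4.05 on 14-day high CEWAF replicate b. Single probes stood apart for SHM_EA_11843 at -6.99 on 7-day low CEWAF replicate c, SHM_EA_31246 at -6.48 on replicate d, SHM_EA_26839 at -9.58 on replicate c, and SHM_EA_11079 at -3.12 and SHM_EA_48726 at -5.49 on 7-day low HEWAF replicate c. The high CEWAF effect differed between 14 and 7 days for 25 probes.

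Other splits of the same arrays were refitted. For high HEWAF, Corexit and low CEWAF at 7 days, 1 of 35 splits, the real one, gave as many calls (6, 69 and 108, highest other 1, 9 and 25). The same held at 14 days for high CEWAF against control and against HEWAF (144 and 148, highest other 67 and 64), a share under 0.05 for each of these 5 taken singly. Adjusted over the 14 such tests the share was 0.0700, so chance is not taken as excluded. Those 14 included the comparisons with 0 calls given below, a count that every split reaches, so the adjusted share rests in part on tests that could not vary. These splits ignore slide, and all 3 female 7-day controls were on slide 1; with slide as a fixed block the calls were 0, 0 and 1 for high HEWAF, Corexit and low CEWAF at 7 days and 53 and 55 at 14 days. Chance was also not excluded for high CEWAF at 7 days (11 calls, 3 of 35 splits, highest other 1345, which points to a structure of the samples), high against low CEWAF (2 calls, 3 of 35, highest other 5) or low CEWAF against low HEWAF (16 calls, 2 of 35, highest other 34). With 0 calls, all 35 splits reached the count for low HEWAF, for high HEWAF at 14 days, for the HEWAF doses and for high CEWAF against high HEWAF at 7 days (highest other 4, 8, 2 and 20), as did all 100 for the high HEWAF day difference (highest other 98). For the high CEWAF day difference 3 of 100 splits gave 25 or more calls, highest other 59, and the adjusted share was also 0.0700, so chance is not taken as excluded there either.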

How the results depend on the processing

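The common floor, the all-probe percentile, the fits without the dim arrays or the outlying array, and the brightness covariate were chosen after seeing the data. The other alternatives were planned. The plan named a 75th percentile without naming its probes, and the shared probes were taken for the main scale because of the shares well above background. With the all-probe percentile low CEWAF at 7 days had 53 higher and 44 lower probes. High CEWAF at 14 days then had 100 higher and 255 lower. Calls at 7 days depended on the background correction, the scaling, the slide, array weights and single arrays. So did those of 14-day high CEWAF, where 144 probes became 1 with normexp background correction, whose offset of 50 shrinks differences of dim probes. Quantile normalisation gave 735, of which 592 were lower. Slide as a fixed block left 53, array weights gave 351, and leaving out single arrays of the compared groups gave 34 to 154. It had at least 1 call under every alternative that kept more than 1 control array. Fits within a slide often had 1 array in a group, taken to vary like the others. Where counts moved by more than 1.5 times they are listed as numbers of probes, with 7 d and 14 d for the days, 'day difference' for the 14-day against 7-day effect, and the cause was not tested. Low signal over background, down to 16.7% of the probes on 1 array, limits the probes that can be measured; the dim arrays below are the 4 whose 75th percentile of signal lay under 50. No named probe changed direction. Gene list alternatives were not run, since no gene names were given, and the value table gave no day differences.

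With normexp background correction: high HEWAF (7 d) 0, Corexit (7 d) 0, low CEWAF (7 d) 0, high CEWAF (7 d) 0, high CEWAF (14 d) 1, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 0, high CEWAF and high HEWAF (14 d) 18, high CEWAF day difference 0. With quantile normalisation: high HEWAF (7 d) 1, Corexit (7 d) 14, low CEWAF (7 d) 16, high CEWAF (7 d) 3, high HEWAF (14 d) 7, Corexit (14 d) 70, high CEWAF (14 d) 735, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 7, high CEWAF and high HEWAF (14 d) 650, high HEWAF day difference 1, Corexit day difference 12, high CEWAF day difference 88. With median centring: high HEWAF (7 d) 1, Corexit (7 d) 11, high CEWAF (7 d) 24, high HEWAF (14 d) 1, high and low CEWAF (7 d) 1, low CEWAF and low HEWAF (7 d) 79, high CEWAF and high HEWAF (7 d) 17, high CEWAF and high HEWAF (14 d) 252, high HEWAF day difference 1, Corexit day difference 1. With the authors' value table: high HEWAF (7 d) 0, Corexit (7 d) 0, low CEWAF (7 d) 59, high CEWAF (7 d) 21, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 25, high CEWAF and high HEWAF (7 d) 1, high CEWAF (14 d) 221. With no filter on dim probes: high HEWAF (7 d) 1, Corexit (7 d) 7, low CEWAF (7 d) 31, high CEWAF (7 d) 3, high CEWAF (14 d) 63, high and low CEWAF (7 d) 1, low CEWAF and low HEWAF (7 d) 3, high CEWAF and high HEWAF (14 d) 65, high CEWAF day difference 1. With probes well above background on all female arrays: high HEWAF (7 d) 2, Corexit (7 d) 28, low CEWAF (7 d) 51, high CEWAF (7 d) 6, high CEWAF (14 d) 30, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 4, high CEWAF and high HEWAF (14 d) 23, high CEWAF day difference 9. With slide as a fixed block: low HEWAF (7 d) 1, high HEWAF (7 d) 0, Corexit (7 d) 0, low CEWAF (7 d) 1, high CEWAF (7 d) 0, high CEWAF (14 d) 53, high and low CEWAF (7 d) 1, low CEWAF and low HEWAF (7 d) 2, high CEWAF and high HEWAF (7 d) 1, high CEWAF and high HEWAF (14 d) 55, high CEWAF day difference 0. For 38 arrays with sex as a covariate: high HEWAF (7 d) 11, Corexit (7 d) 108, high CEWAF (7 d) 30, high CEWAF day difference 50. For 38 arrays without a sex term: low HEWAF (7 d) 1, high HEWAF (7 d) 12, Corexit (7 d) 122, high CEWAF (7 d) 61, high CEWAF (14 d) 220, high CEWAF day difference 62. With groups compared alone: high HEWAF (7 d) 19, Corexit (7 d) 0, high CEWAF (7 d) 0, high CEWAF (14 d) 48, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 0, Corexit day difference 56. With an eBayes trend and robust prior: high HEWAF (7 d) 3, high CEWAF (7 d) 5, high and low CEWAF (7 d) 1, high CEWAF day difference 15. With array weights: low HEWAF (7 d) 71, high HEWAF (7 d) 1688, Corexit (7 d) 2418, low CEWAF (7 d) 1999, high CEWAF (7 d) 1986, Corexit (14 d) 14, high CEWAF (14 d) 351, high and low CEWAF (7 d) 37, low CEWAF and low HEWAF (7 d) 226, high CEWAF and high HEWAF (7 d) 161, high CEWAF and high HEWAF (14 d) 574, high HEWAF day difference 13, Corexit day difference 586, high CEWAF day difference 731. Within slide 1: low HEWAF (7 d) 2, high HEWAF (7 d) 1, high CEWAF (7 d) 577, high and low HEWAF (7 d) 1. Within slide 4: high HEWAF (14 d) 3, high CEWAF (14 d) 23, high CEWAF and high HEWAF (14 d) 61. Within slide 6: high HEWAF (14 d) 4. Within slide 3: high and low CEWAF (7 d) 0. Within slide 2: high CEWAF and high HEWAF (7 d) 2. With the 75th percentile over all probes: high HEWAF (7 d) 1, Corexit (7 d) 8, high CEWAF (7 d) 24, Corexit (14 d) 1, high CEWAF (14 d) 355, high and low CEWAF (7 d) 1, low CEWAF and low HEWAF (7 d) 88, high CEWAF and high HEWAF (7 d) 22, high CEWAF and high HEWAF (14 d) 261, high HEWAF day difference 1, Corexit day difference 1, high CEWAF day difference 98. With a common floor: low HEWAF (7 d) 1, high HEWAF (7 d) 14, Corexit (7 d) 124, high CEWAF (7 d) 85, high HEWAF (14 d) 1, Corexit (14 d) 7, high and low CEWAF (7 d) 0, low CEWAF and low HEWAF (7 d) 34, high CEWAF and high HEWAF (7 d) 10, high CEWAF and high HEWAF (14 d) 83, Corexit day difference 17. Without the dim arrays: Corexit (7 d) 38, low CEWAF (7 d) 221, high CEWAF (7 d) 51, high CEWAF (14 d) 248, high and low CEWAF (7 d) 9, high CEWAF day difference 170. Without the outlying array: high HEWAF (7 d) 10, Corexit (7 d) 307, low CEWAF (7 d) 329, high CEWAF (7 d) 289, Corexit (14 d) 1, high and low CEWAF (7 d) 1, low CEWAF and low HEWAF (7 d) 78, high CEWAF and high HEWAF (7 d) 18, high HEWAF day difference 1, Corexit day difference 59, high CEWAF day difference 217. With array brightness as a covariate: low CEWAF (7 d) 205, high CEWAF (7 d) 21, Corexit (14 d) 14, high and low CEWAF (7 d) 5, Corexit day difference 62, high CEWAF day difference 107.

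With tank letter and day as a replicate block, counts were low HEWAF (7 d) 1, high HEWAF (7 d) 3, Corexit (7 d) 18, low CEWAF (7 d) 49, high CEWAF (7 d) 6, low CEWAF and low HEWAF (7 d) 9; the block moved no other count by over 1.5 times. The 71 same-letter pairs of arrays from different groups of a day had a mean correlation of deviations of 0.0170. For the 211 other pairs it was -0.00343, and 22 and 63 pairs lay over 0.1. These means were not tested and pairs across days were not compared, so whether letters mark related fish stays open.

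Leaving out each array of the compared groups in turn gave ranges of 0 for low HEWAF (7 d), 0 to 10 for high HEWAF (7 d), 1 to 53 for Corexit (7 d), 0 to 108 for low CEWAF (7 d), 0 to 289 for high CEWAF (7 d), 0 for high HEWAF day difference, 0 to 59 for Corexit day difference, 0 to 217 for high CEWAF day difference, 0 to 1 for high and low HEWAF (7 d), 5 to 22 for low CEWAF and low HEWAF (7 d), 0 to 18 for high CEWAF and high HEWAF (7 d), 0 to 5 for high and low CEWAF (7 d), 0 for high HEWAF (14 d), 0 to 76 for Corexit (14 d), 34 to 154 for high CEWAF (14 d), 55 to 236 for high CEWAF and high HEWAF (14 d). Arrays of other groups also enter through the shared spread, and the counts without the outlying array, 7-day high CEWAF replicate c, lay above these ranges for several comparisons it took no part in, with 204 for high CEWAF (14 d).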

Other observations

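Sets of probes that varied together between fish of a group were taken from the 400 most variable probes, of which 13 (3.25%) were called in a treatment comparison, against 296 (3.99%) of all 7422. A wide spread within groups makes a call less likely. Of the 115 probes in the largest set 1 was called, and of the sets of 38 and 26 probes 0 were called. The set of 115 averaged 3.61 and 3.31 in 7-day control replicates a and b and 0.704 in replicate c, all relative to the array median. It averaged 3.30 in 7-day high HEWAF replicate a, 4.70 in 7-day high CEWAF replicate c, 2.73 in 7-day Corexit replicate a and 3.54 in 14-day Corexit replicate c. The male fish had 1.31 at 7 days and 0.470 at 14 days.

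The probes lower in 14-day high CEWAF, 43 in number, averaged -0.198 ± 0.158 (SD, n = 4) there, 1.30 ± 0.286 (SD, n = 4) in high HEWAF and 1.83 ± 0.404 (SD, n = 3) in control. Corexit at 14 days had 0.415 and 0.320 on its 2 arrays. The 43 probes were chosen by the comparison of high CEWAF with control, so those 2 means had to differ. On the high CEWAF arrays 16.7% to 25.3% of all probes were well above background. A mean near the array median can therefore lie near background there, and the test of a signal floor covered the higher probes only. The probes higher in 14-day high CEWAF did not separate high CEWAF from high HEWAF at 7 days (difference -0.112, exact two-sided permutation p = 0.771, n = 4 and 4).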
